A study of Homo sapiens with 10 samples.

How the data were processed

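Transcript levels were measured on Clariom S human arrays in SH-SY5Y cells, 10 arrays in 5 labelled groups of 2. The labels give BBEE at 0.2 mg/mL, LPS at 1 ng/mL, pretreatment for 24 h and LPS for 24 h, and give no dose of 2-AB. The labels' protocols say that BBEE was extracted with ethanol. The meaning of the abbreviations BBEE and 2-AB is not stated in the files, and the authors' workbook calls the extract Kurokojiro. The design text speaks of duplicate RNA samples and no file says that the replicates were separate cultures. The p-values therefore measure only the spread between these arrays.

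Per the submitters' processing notes, the authors normalized the arrays with RMA in Transcriptome Analysis Console 4, while the design text names version 4.0.1 and the SST-RMA form, and the deposited values of the series matrix and of the single-array table are log2 intensities. The deposited comparison tables hold, per the file headers, group averages in log2 and a score, the signed linear fold change the authors computed from those averages, written as minus the inverse where the level fell. Their p-value and FDR columns are p-values the authors computed and deposited. The comparison tables list only genes chosen by p-value and fold, at least 1.5-fold for the extract tables and 1.2-fold for the 2-AB tables.

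The series matrix held 2 sets with different levels, medians from 6.783 to 6.823 in the 6 arrays of the extract set and from 7.349 to 7.418 in the 4 arrays of the 2-AB set. Correlations between arrays ran from 0.9887 to 0.9932 within the extract set, from 0.9862 to 0.9944 within the 2-AB set and from 0.9411 to 0.9539 between the sets. No file states that the sets were normalized apart, which was inferred from these levels and from the single-array table holding only the extract set. The single-array table held 8 arrays, the 6 of the extract set (differing by at most 0.0503 from the matrix) and 2 control columns that match no array of the series. For LPS against control, BBEE against control and the interaction, the fit therefore used the 8 arrays of the single-array table. This was chosen after the files were seen, and the planned fit against the arrays labelled noLPS_medium is given as an alternative. The other comparisons used the 10 arrays of the series matrix as planned.

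Of 24351 features, 2903 control features were not tested and 21448 transcript clusters were. Symbols came from the authors' table: 20406 clusters carried 1 symbol and 1042 several, and 815 circular RNA or transcript models were not named, a refinement made after the files were seen. Of 18586 distinct symbols, 18537 were found in the RefSeq table, and of 654 listed genes 591 were matched. A listed gene with several clusters was read from the one with the highest mean.

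Group means were fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes without trend) and p-values adjusted by the Benjamini-Hochberg method over all clusters, with adjusted p under 0.05 as the threshold. No minimum fold was applied. The 30 gene lists were tested with camera at a correlation between genes of 0.01, and the adjusted p with an estimated correlation is given beside each list that passed. In comparisons within a set, lists not named in the report did not pass. The 95th percentile of 391 olfactory receptor clusters was 5.547 in the extract set and 5.791 in the 2-AB set (log2), and a lower group mean within that range gives a fold as a lower bound. Gene lists kept members whose means all lay within that range, so list counts include genes whose direction cannot be read. The single-array table holds no control features, so spiked controls were not checked for the control columns. The arrays separated 2197 positive from 612 negative control features with an area under the curve of 0.962 to 0.97. With 2 arrays per group, the number of arrays limits precision: the median standard error of a log2 difference was 0.237. Figures were drawn with Python 3.11.15.

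Named genes followed a rule: in each direction the 10 passing clusters of exactly 1 symbol with the largest change whose arrays in a group all lay above those of the other group (for the interaction by adjusted p alone), filled to 5 by smallest p-value where fewer passed and then said not to pass, up to 4 members with the smallest p-value of each list, and a fixed set of inflammatory, antioxidant and neuronal genes. The text names fewer than the rule allows. The groups, comparisons, threshold, lists, naming rule and alternative settings not marked otherwise were set before the data were examined.

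The method was tested on simulated data with 100 clusters changed by log2 1 and 100 by log2 2. At log2 2 it called 100 in each comparison of 2 groups and 98 in the interaction. At log2 1 it called 44 (LPS), 61 (BBEE), 53 (BBEE under LPS), 49 (LPS under BBEE), 5 (interaction) and 49 (2-AB set), with 0 of the wrong sign and 4 to 14 unchanged clusters called. A smaller change can therefore be present and not called.

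Alternatives tried were the single-array table, quantile and cyclic loess normalization, a filter on dim clusters (13901 of 21448 kept in the matrix, 13289 in the single-array table), only the compared groups, an intensity trend, a replicate block, each array left out in turn, and camera with an estimated correlation and fry in place of camera. Relations between comparisons were set beside 100 simulations without any effect, with noise drawn independently for each cluster. Differences between the sets were not read as biology, raw array files were not reprocessed, and protein or cell measurements were not analysed here.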

Results

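SH-SY5Y neuroblastoma cells were exposed to lipopolysaccharide (LPS), a bacterial cell-wall component that starts inflammatory signalling, with or without pretreatment with the extract BBEE or with 2-AB. The 10 arrays fell into an extract set (6 arrays) and a 2-AB set (4 arrays) whose median levels lay apart, read here as separate normalization. Joint quantile normalization still left 9087 clusters different between arrays of the 2 sets, so a shift of whole array distributions was not the whole difference. It acted on values already summarized per cluster, so other effects of separate normalization were not excluded. The untreated cells of the extract set were present only as 2 control columns of the authors' deposited single-array table, and these columns served as the control below.

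LPS raised inflammatory signalling genes in the extract set. CCL2, a chemokine that draws in monocytes (chromosome 17, 34255285 to 34257203, GRCh38.p14 RefSeq table), rose. VCAM1 (a vascular adhesion molecule for leukocytes), TNFRSF9 (a co-stimulatory receptor of the TNF receptor family) and CSF1 (the growth factor of macrophages) rose as well. SOD2, the mitochondrial superoxide dismutase, CCL5, a chemokine for T cells, TNC, a matrix glycoprotein made at sites of injury, and the semaphorin co-receptor NRP2 followed. CCL2 stood at 10.98 ± 0.04 with LPS and 4.19 ± 0.09 without (log2 intensity, mean ± SD, n = 2 arrays per group throughout), a log2 difference of 6.79 (standard error 0.26, adjusted p = 3.3e-08, limma), or at least 43.1-fold. VCAM1 stood at 8.85 ± 0.08 against 4.29 ± 0.16 (adjusted p = 1.35e-07, at least 9.84-fold) and TNFRSF9 at 9.15 ± 0.25 against 4.33 ± 0.10 (adjusted p = 3.39e-05, at least 12.1-fold). CSF1 rose from 5.66 ± 0.33 to 9.12 ± 0.50 (adjusted p = 6.24e-05), SOD2 from 9.88 ± 0.19 to 12.46 ± 0.09 (adjusted p = 0.000116), and TNC from 6.88 ± 0.30 to 9.29 ± 0.26 (adjusted p = 0.00152). CCL5 rose at least 3.48-fold (adjusted p = 0.000123), NRP2 at least 3.3-fold (adjusted p = 0.00176), the stress-inducible survival gene IER3 at least 1.87-fold (adjusted p = 0.00221), the soluble pattern-recognition gene PTX3 at least 2.91-fold (adjusted p = 0.0138) and the stress-induced gene FAM129A at least 1.96-fold (adjusted p = 0.0221). A further set of passing genes was chosen for naming after its values were seen: the interferon-inducible chemokine CXCL10 (5.58 with LPS, about the olfactory line, adjusted p = 0.00128), CPT1A, which brings fatty acids into mitochondria (2.02, adjusted p = 0.00167), the TNF receptor adaptor TRAF1 (adjusted p = 0.0138) and the adhesion molecule ICAM1 (adjusted p = 0.0158). The "at least" folds divide the higher group mean by the larger of the gene's own lower mean and the 95th percentile of 391 olfactory receptor clusters (5.55 on the log2 scale), since the lower mean lay in that dim range. IL6 (3.33 ± 0.29 with LPS), IL1B, TNF, PTGS2 and the LPS receptor gene TLR4 (4.94 ± 0.49) lay within the olfactory range, where a change cannot be read.

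Among the gene lists, inflammatory NF-kB targets were higher with LPS in 24 of 29 members (median 0.75). The 29 include IL6, IL1B, TNF and PTGS2, which lay within the olfactory range, where a direction cannot be read. Of the 29, 7 passed as higher when adjusted over all genes and 16 when adjusted over the list alone (camera adjusted p = 3.26e-18, and adjusted p = 0.0151 with an estimated correlation). Cholesterol synthesis genes were higher in 22 of 23 members (median 0.40), 0 adjusted over all genes and 2 adjusted over the list alone (camera adjusted p = 1.03e-06, but adjusted p = 0.297 with an estimated correlation). Genes of the integrated stress and unfolded protein responses were higher in 21 of 26 (median 0.34), 0 adjusted over all genes and 0 adjusted over the list alone (camera adjusted p = 0.00653, but adjusted p = 0.297 with an estimated correlation). Immediate early genes were higher in 14 of 20, with IER3 the 1 member past adjusted over all genes and adjusted over the list alone (camera adjusted p = 0.0473, but adjusted p = 0.306 with an estimated correlation). Interferon-stimulated genes (camera adjusted p = 0.931) and NRF2 antioxidant targets (camera adjusted p = 0.646) did not pass. In total 18 of 21448 transcript clusters were higher and 0 lower (limma, adjusted p under 0.05), with 1641 at unadjusted p under 0.05 where 1072.4 were expected by chance. Leaving out 1 array at a time left 9 to 15 calls, the lowest without control column 2.

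**Figure D1:**
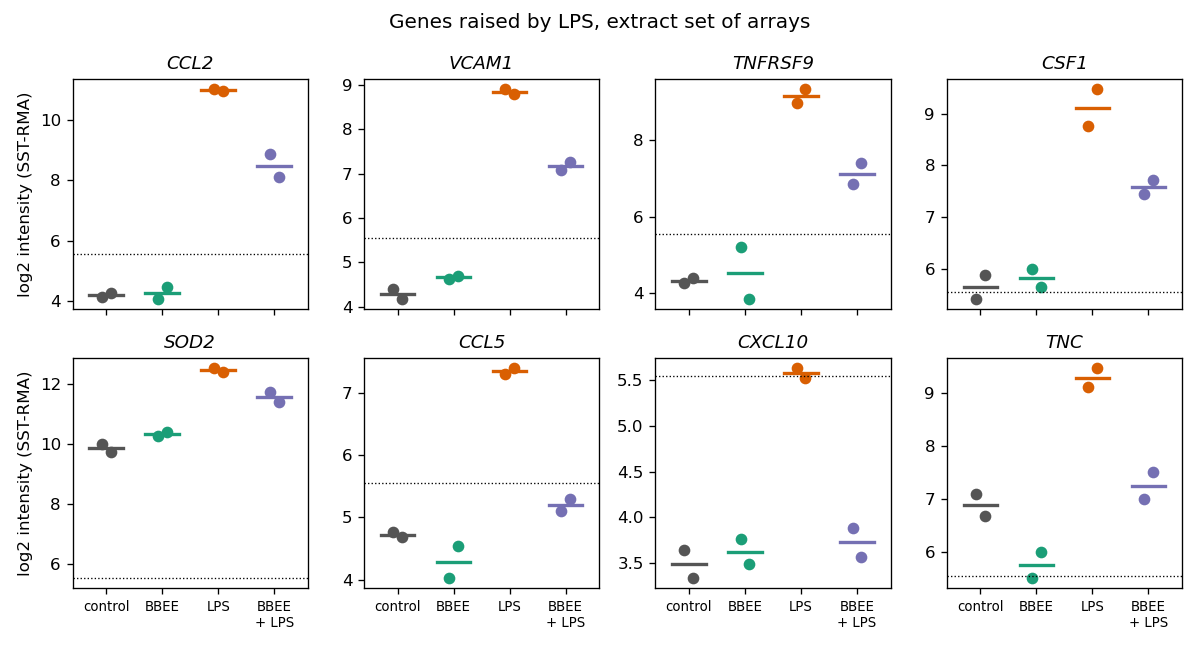
Genes raised by LPS in the extract set. Each point is 1 array, each bar the mean of 2 arrays, and the dotted line the 95th percentile of olfactory receptor clusters. Log2 intensity axes differ between panels and do not start at 0.

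Set against the control columns, BBEE alone lowered a sterol-sensing gene and raised a gene of fatty acid burning. CPT1A, the gate through which long-chain fatty acids enter mitochondria (chromosome 11, 68754620 to 68844277, GRCh38.p14), rose. INSIG1, an endoplasmic reticulum protein that senses sterols and is itself switched on by SREBP factors (chromosome 7, 155297878 to 155310235), fell. Genes of cholesterol synthesis and of fatty acid synthesis passed as lower groups with camera at its preset correlation, but each had adjusted p = 0.0659 with an estimated correlation. CPT1A stood at 11.09 ± 0.18 with BBEE and 8.92 ± 0.31 without (log2 difference 2.17, standard error 0.23, adjusted p = 0.00648, limma, 4.5-fold). INSIG1 stood at 8.52 ± 0.17 against 10.19 ± 0.08 (log2 difference -1.67, adjusted p = 0.03). Cholesterol synthesis genes were lower in 21 of 23 members (median -0.94). Adjusted over all genes 1 passed, and adjusted over the list alone 19 passed (camera adjusted p = 3.26e-20, but adjusted p = 0.0659 with an estimated correlation). Fatty acid synthesis genes were lower in 11 of 11 (median -0.45), 0 adjusted over all genes and 4 adjusted over the list alone (camera adjusted p = 4.84e-07, but adjusted p = 0.0659 with an estimated correlation). Of single members, DHCR7, the last enzyme of cholesterol synthesis, stood at 12.66 ± 0.23 against 13.85 ± 0.09 without passing (adjusted p = 0.156), and the isoprenoid enzyme IDI1 did not pass either (-1.44, adjusted p = 0.115). G1/S and replication genes were lower in 20 of 25 (median -0.29), 0 adjusted over all genes and 6 adjusted over the list alone (camera adjusted p = 2.24e-05, but adjusted p = 0.245 with an estimated correlation). WEE1, a kinase that holds back mitotic entry, stood at 9.17 ± 0.09 against 10.61 ± 0.26 (adjusted p = 0.0781) and the replication clamp PCNA at 10.83 ± 0.26 against 11.89 ± 0.20 (adjusted p = 0.218), neither passing. Fibroblast marker genes were lower in 9 of 11 (median -0.17), 0 adjusted over all genes and 2 adjusted over the list alone (camera adjusted p = 0.0407, but adjusted p = 0.592 with an estimated correlation). Of its members, FAP (3.07 against 4.275), which had the smallest p-value, and DCN (4.97 against 5.415) lay within the olfactory range in both groups, where a change cannot be read. NF-kB targets showed no shift with BBEE alone (14 higher and 15 lower, camera adjusted p = 0.727), nor did NRF2 targets (camera adjusted p = 0.691). CPT1A and INSIG1 were the only calls (1 higher, 1 lower, 2256 clusters at unadjusted p under 0.05), and 0 passed without control column 2 or either BBEE array, or with only the compared groups in the fit (limma, 2328 at unadjusted p under 0.05). Both calls rest on the control columns: CPT1A stood at 11.36 ± 0.17 and INSIG1 at 8.26 ± 0.59 in the arrays labelled noLPS_medium of the other set, against which BBEE gave -0.27 and 0.26. Those arrays differed from the control columns in 12029 clusters, so they cannot decide the effect of BBEE. Under LPS, without the control columns, INSIG1 also fell with BBEE (-1.88, adjusted p = 0.0212, limma). CPT1A stood at 11.12 with BBEE and LPS and 10.94 with LPS.

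Under LPS, BBEE pretreatment lowered the chemokine genes CCL2 and CCL5 and the sterol pathway. DKK1, a secreted Wnt antagonist (chromosome 10, 52314281 to 52317657), and TNC fell as well. Within sterol synthesis INSIG1, MSMO1, MVD, HMGCS1 and DHCR7 fell, with PGRMC1 and TMEM97, both membrane proteins that bind or traffic sterols. TXLNB, a taxilin of muscle and other tissues, rose. CCL2 stood at 8.48 ± 0.55 with BBEE and LPS and 10.98 ± 0.04 with LPS alone (log2 difference -2.50, standard error 0.26, adjusted p = 0.00339, limma, 5.65-fold), still above the control level. DKK1 stood at 5.78 ± 0.07 against 7.81 ± 0.06 (-2.03, adjusted p = 0.00238), TNC at 7.25 ± 0.36 against 9.29 ± 0.25 (adjusted p = 0.00958) and CCL5 at 5.20 ± 0.14 against 7.35 ± 0.06 (-2.15, adjusted p = 0.0373, at least 3.48-fold). CXCL10 fell from 5.58 ± 0.08, about the olfactory line, to 3.73 ± 0.22 (adjusted p = 0.00526, at least 1.02-fold). HMGCS1, which commits carbon to sterol synthesis, stood at 13.23 ± 0.12 against 14.68 ± 0.14 (-1.44, adjusted p = 0.0212), MSMO1 at 14.41 ± 0.09 against 15.95 ± 0.06 (adjusted p = 0.0212), MVD at 7.97 ± 0.03 against 9.81 ± 0.53 (adjusted p = 0.0212) and DHCR7 at 12.72 ± 0.04 against 14.27 (adjusted p = 0.0373). INSIG1 fell by 1.88 (adjusted p = 0.0212), PGRMC1 by 1.60 (adjusted p = 0.0152) and TMEM97 by 1.66 (adjusted p = 0.0283). TXLNB stood at 6.38 ± 0.18 against 5.05 ± 0.23 (adjusted p = 0.031, at least 1.78-fold). VCAM1 (7.18 ± 0.12 against 8.84 ± 0.08, adjusted p = 0.0929) and IER3 (adjusted p = 0.0706) did not pass. The spread in this fit came from all 10 arrays, and VCAM1 varied most in the 2-AB set (SD 0.62 and 0.74).

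Cholesterol synthesis genes were lower in 22 of 23 members with BBEE under LPS (median -1.21), 9 past adjusted over all genes and 21 adjusted over the list alone (camera adjusted p = 1.11e-30, and adjusted p = 0.03 with an estimated correlation). Fatty acid synthesis genes were lower in 11 of 11 (median -0.64), 2 adjusted over all genes and 6 adjusted over the list alone (camera adjusted p = 4.67e-08, and adjusted p = 0.03 with an estimated correlation). NF-kB targets were lower in 24 of 29 (median -0.33), 3 adjusted over all genes and, adjusted over the list alone, 10 lower and 1 higher (camera adjusted p = 3.79e-06, and adjusted p = 0.03 with an estimated correlation). Metallothionein genes, which bind zinc and copper, were lower in 9 of 10 (median -0.49), 0 adjusted over all genes and 3 adjusted over the list alone (camera adjusted p = 0.000131, but adjusted p = 0.199 with an estimated correlation). Neurotrophin receptor and ligand genes were lower in 12 of 18 (median -0.36), 0 adjusted over all genes and 3 adjusted over the list alone (camera adjusted p = 0.00201, but adjusted p = 0.092 with an estimated correlation). G1/S genes were lower in 21 of 25, 0 adjusted over all genes and 0 adjusted over the list alone (camera adjusted p = 0.000571, but adjusted p = 0.269 with an estimated correlation). Proteasome genes were lower in 20 of 28, 0 adjusted over all genes and 2 adjusted over the list alone (camera adjusted p = 0.00435, but adjusted p = 0.516 with an estimated correlation). Ribosomal protein genes were lower in 18 of 23 (median -0.20), 0 adjusted over all genes and 1 adjusted over the list alone (camera adjusted p = 0.00469, but adjusted p = 0.622 with an estimated correlation), and oxidative phosphorylation genes in 22 of 31, 0 adjusted over all genes and 2 adjusted over the list alone (camera adjusted p = 0.0102, but adjusted p = 0.622 with an estimated correlation). Fibroblast markers were lower in 10 of 11, 0 adjusted over all genes and 0 adjusted over the list alone (camera adjusted p = 0.038, but adjusted p = 0.516 with an estimated correlation). Among them DCN (4.835 against 5.475) lay within the olfactory range in both groups. In all 2 clusters were higher and 26 lower (limma). The spiked poly-A controls, added before labelling, stood at 6.78 ± 0.26 with BBEE and LPS and 5.69 ± 0.15 with LPS, and the hybridization controls at 10.34 ± 0.18 and 10.40 ± 0.07, so a difference in RNA input or labelling along with this comparison was not excluded. Leaving out single arrays left 1 to 3 calls, and a fit on only these 2 groups left 7, 6 of them shared.

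**Figure D2:**
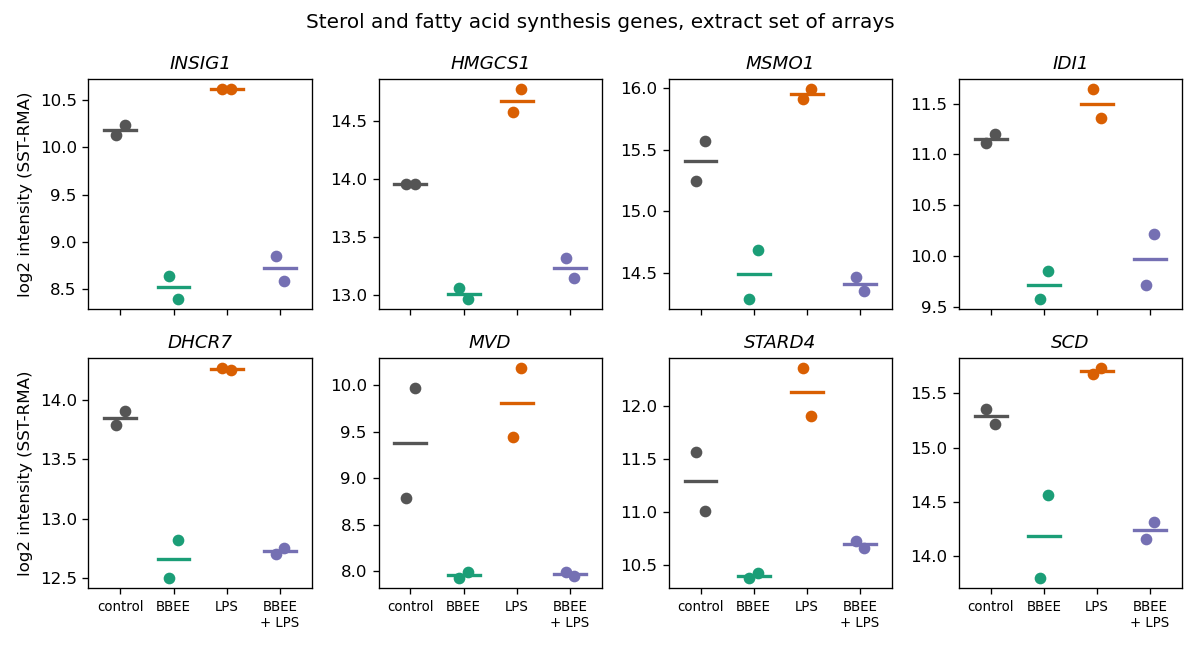
Sterol and fatty acid synthesis genes in the extract set. Each point is 1 array and each bar the mean of 2 arrays. Log2 intensity axes differ between panels and do not start at 0.

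LPS still raised inflammatory genes in cells pretreated with BBEE. CCL2 rose from 4.26 ± 0.28 with BBEE alone to 8.48 ± 0.55 with BBEE and LPS (log2 difference 4.22, standard error 0.26, adjusted p = 1.5e-05, limma, at least 7.63-fold). VCAM1 (7.18 ± 0.12 against 4.67 ± 0.05, at least 3.1-fold, adjusted p = 0.0528), TNFRSF9 (at least 2.97-fold, adjusted p = 0.061), CSF1 (1.76, adjusted p = 0.061) and SOD2 (1.23, adjusted p = 0.708) did not pass. This fit took its spread from all 10 arrays, unlike the 8-array fit of LPS against control. The standard errors of VCAM1 and SOD2 were 0.331 and 0.327 here against 0.208 and 0.22 there. Those of TNFRSF9 and CSF1 were close (0.362 and 0.252 against 0.354 and 0.274). DSCAM, a neuronal adhesion gene (lower by at least 1.6-fold, adjusted p = 0.228), and SRD5A1, a steroid reductase gene (-1.08, adjusted p = 0.381), did not pass either. NF-kB targets were higher in 22 of 29 members (median 0.39), 1 adjusted over all genes and 7 adjusted over the list alone (camera adjusted p = 1.18e-09, and adjusted p = 0.0203 with an estimated correlation). Oxidative phosphorylation genes were lower in 27 of 31 (median -0.21), 0 adjusted over all genes and 0 adjusted over the list alone (camera adjusted p = 0.000185, but adjusted p = 0.96 with an estimated correlation). Ribosomal protein genes were lower in 22 of 23 (median -0.20), 0 adjusted over all genes and 0 adjusted over the list alone (camera adjusted p = 0.00363, but adjusted p = 0.96 with an estimated correlation). Neurotrophin genes were lower in 15 of 18 (median -0.27), 0 adjusted over all genes and 0 adjusted over the list alone (camera adjusted p = 0.00976, but adjusted p = 0.265 with an estimated correlation). Cholesterol synthesis genes did not pass here (12 higher, 11 lower, camera adjusted p = 0.863). CCL2 was the only call of 21448 clusters in this 10-array fit, with 1382 at unadjusted p under 0.05. The same comparison fitted on the 8 arrays of the single-array table called 3 clusters, CCL2 among them. The spiked poly-A controls differed here too (6.78 ± 0.26 against 6.06 ± 0.22 with BBEE alone), so a difference in RNA input or labelling was not excluded.

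Whether BBEE changed the size of the LPS step was tested as an interaction, and no single gene passed. VCAM1 (-2.05, standard error 0.30, adjusted p = 0.113) and CCL2 (-2.58, standard error 0.37, adjusted p = 0.113) came nearest, followed by CPT1A (-1.99, adjusted p = 0.176). Without LPS, VCAM1 and CCL2 lay within the olfactory range, so the size of their terms is not exact, and CXCL10 was too dim for its term to be read. Among positive terms the orphan receptor GPR157 (1.92, adjusted p = 0.289) and TXLNB (1.72, adjusted p = 0.289) came nearest. CPT1A was low only in the control columns, at 8.92 against 11.09 with BBEE, 10.94 with LPS and 11.12 with both. Of the lists, NF-kB targets had negative terms in 19 of 29 members (median -0.46), 0 adjusted over all genes and, adjusted over the list alone, 5 lower and 1 higher (camera adjusted p = 0.00113, but adjusted p = 0.287 with an estimated correlation). Cholesterol synthesis genes had negative terms in 19 of 23 (median -0.40), 0 adjusted over all genes and 0 adjusted over the list alone (camera adjusted p = 0.0121, but adjusted p = 0.578 with an estimated correlation). Metallothionein genes had them in 9 of 10 (median -0.21), 0 adjusted over all genes and 3 adjusted over the list alone (camera adjusted p = 0.0212, but adjusted p = 0.578 with an estimated correlation). Limma called 0 clusters, with 1792 at unadjusted p under 0.05. The median standard error was 0.34 here against 0.24 in a comparison of 2 groups.

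CCL2, CXCL10, CCL5, TNC and CSF1 were both raised by LPS and lower with BBEE under LPS, 5 shared calls where independent lists would share 0.0218. Both comparisons used the same LPS arrays, which alone pulls their differences in opposite directions. Across 21448 clusters the LPS effect and the BBEE effect under LPS correlated at -0.49, and simulations with no effect gave -0.50 (range -0.51 to -0.49). Their covariance was -0.0533, against -0.0311 in the simulations. INSIG1 fell with BBEE both without and with LPS, the 1 shared call of those comparisons, which shared no array. Their correlation was 0.149, where simulations with no effect ranged from -0.021 to 0.016. CCL2 was the 1 call LPS raised both without and with BBEE. That overlap set 18 calls of an 8-array fit beside 1 call of a 10-array fit whose spread includes the 2-AB set, so it is not a like comparison. Across clusters these LPS effects, which shared no array, correlated at -0.056, where simulations with no effect ranged from -0.02 to 0.019. The simulations drew noise independently for each cluster, so noise shared between clusters would widen all of these ranges. Whether 0.149 or -0.056 lies beyond chance was therefore not settled.

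The arrays of the 2-AB set differed in CD9 and MTRNR2L5, but their labels conflict, so the direction of every difference here is unsettled. CD9, a tetraspanin that organizes membrane proteins (chromosome 12, 6199946 to 6238266), was higher in the arrays labelled 2AB_LPS than in the arrays labelled noLPS_medium. MTRNR2L5, a humanin-like sequence near-identical to mitochondrial 16S RNA, was lower. CD9 stood at 11.18 ± 0.40 against 8.47 ± 0.02 (log2 difference 2.71, standard error 0.24, adjusted p = 0.00111, limma, 6.56-fold) and MTRNR2L5 at 6.65 ± 0.29 against 8.66 ± 0.35 (-2.01, adjusted p = 0.0177). All 10 of 10 MTRNR2L features were lower (median -1.33), 1 of them passing. The mitochondrial carrier homologue MTCH2 (14.38 ± 0.04 against 12.75 ± 0.50) and the protocadherin PCDHB11 (10.96 ± 0.23 against 12.60 ± 0.45) each had an adjusted p of 0.0502 and did not pass. CCL2 stood at 8.85 ± 0.16 in the arrays labelled 2AB_LPS and 8.53 ± 0.02 in those labelled noLPS_medium. Histone genes of DNA replication were lower in 23 of 25 members (median -0.51), 0 adjusted over all genes and 6 adjusted over the list alone (camera adjusted p = 2.74e-08, but adjusted p = 0.729 with an estimated correlation). Proteasome genes were higher in 24 of 28 (median 0.28, camera adjusted p = 0.00717), cholesterol synthesis genes in 20 of 23 (median 0.34, camera adjusted p = 0.00858), and glycolysis and hypoxia genes in 18 of 22 (median 0.25, camera adjusted p = 0.0165). In each of these lists 0 members passed adjusted over all genes and 0 adjusted over the list alone, and adjusted p = 0.729 with an estimated correlation. NF-kB targets did not shift (16 of 29 higher, camera adjusted p = 0.979). In all 1 cluster was higher and 1 lower (limma, 2887 at unadjusted p under 0.05), and leaving out noLPS_medium replicate 1 left 218. With only these groups in the fit, limma called 0 (2665 at unadjusted p under 0.05), and the spiked and hybridization controls also differed between the groups (6.51 ± 0.51 and 11.81 ± 0.43 in the arrays labelled noLPS_medium, 4.94 ± 0.14 and 10.69 ± 0.07 in those labelled 2AB_LPS).

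**Figure D3:**
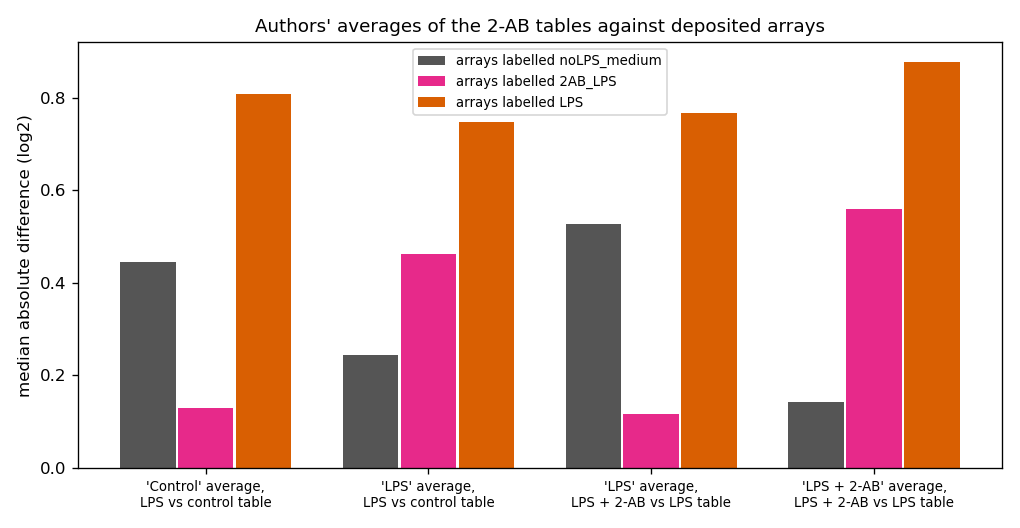
Median absolute log2 difference between each average in the authors' deposited 2-AB tables and the arrays carrying each label. The smaller the bar, the nearer the average lay to those arrays.

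The label conflict of the 2-AB set lay in the labels themselves and in the deposited values. The sample titles of the arrays labelled noLPS_medium name a 2-AB pretreatment without LPS, whereas their descriptions name medium without LPS, and a source field of the arrays labelled 2AB_LPS names BBEE. In the authors' deposited table of LPS with 2-AB against LPS, the average named LPS+2-AB lay nearest the arrays labelled noLPS_medium (median absolute difference 0.142, against 0.56 from the arrays labelled 2AB_LPS). The average named LPS in the authors' deposited table equalled the average named Control of the authors' other 2-AB table in 712 of 712 shared rows. CD9 in the authors' deposited table of LPS with 2-AB against LPS had a fold of -5.43 (FDR 0.0042), and MTRNR2L5 in the authors' deposited table one of 4.04 (FDR 0.0362), opposite in sign to the labelled difference. The labelled difference is 2AB_LPS minus noLPS_medium, by name another contrast than LPS with 2-AB against LPS. Across 4187 rows of the authors' deposited table, chosen by p-value and fold, the correlation with the labelled difference was -0.944. These signs and this correlation follow from which arrays the averages lay nearest and are no separate evidence.

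Comparisons across the sets were computed as planned, but set and treatment cannot be told apart in them and no biology is drawn from them. The arrays labelled 2AB_LPS against those labelled LPS gave 9630 clusters higher and 1908 lower (limma), among them 120 of 391 olfactory receptor clusters, and BBEE with LPS against the arrays labelled 2AB_LPS gave 1868 higher and 9499 lower, with 117 olfactory receptor clusters.

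For the extract set, the refitted differences can be set beside the authors' deposited tables of chosen genes. CPT1A in the authors' deposited table of BBEE against control had a fold of 4.33 (FDR 8e-04) and INSIG1 in the authors' deposited table one of -3.21 (FDR 0.0033). CCL2 in the authors' deposited table of LPS against control had a fold of 109.07 (FDR 1.91e-08), and VCAM1 in the authors' deposited table one of 24.83 (FDR 5.3e-09), both ratios taken against signals in the olfactory range. For BBEE under LPS, the authors' deposited table gave CCL2 a fold of -5.45 (FDR 0.0055), VCAM1 -3.02 (FDR 0.0044), TNFRSF9 -3.58 (FDR 0.0426) and CXCL10, dim here, -3.12 (FDR 0.062). VCAM1 and TNFRSF9 thus passed in the authors' deposited table and not here, while CXCL10 passed here and not in the authors' deposited table. The fit here took its spread from all 10 arrays, the 2-AB set among them. Whether that made the difference was not tested. The authors' deposited tables of the extract set held 7 (BBEE against control), 24 (LPS against control) and 48 (BBEE under LPS) clusters with FDR under 0.05.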

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

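The tests on the histone genes, the fibroblast collagens and the cell state were chosen only after the results were seen, while the test on separate normalization was written down before its result.

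NF-kB target genes, cholesterol synthesis genes and metallothionein genes drew attention because their LPS step differed between cells with and without BBEE, although no single gene did. The interaction gave camera adjusted p values of 0.00113 for NF-kB targets (19 of 29 lower), 0.0121 for cholesterol synthesis (19 of 23 lower) and 0.0212 for metallothioneins (9 of 10 lower). With an estimated correlation the values were 0.287, 0.578 and 0.578. For NF-kB targets the median LPS step was 0.75 without BBEE and 0.395 with it, and for cholesterol synthesis 0.395 and 0.01. All 18 clusters raised by LPS had a smaller step with BBEE (median 2.26 against 0.893), but they were chosen on the same LPS arrays, which favours a smaller step elsewhere.

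Between the control columns of the extract set and the arrays labelled noLPS_medium, 12029 clusters differed. Quantile normalization of 12 arrays together moved the directions, from 9940 higher and 2089 lower to 4479 higher and 4608 lower, a count of 9087 or 75.54 percent. Of the calls made as deposited, 6563 were kept in the same direction (54.56 percent) and 2524 calls were new, where separate normalization as the whole cause was predicted to leave under 5 percent. That prediction covers only a shift of whole array distributions. The values were already summarized per cluster before this step, so other effects of separate normalization were not excluded. An admixture of fibroblasts was tested on COL1A1, COL1A2 and COL6A3, whose mean difference was 0.09 (SD 0.705), but COL6A3 lay at background and DCN (4.63), ACTA2 (2.95) and LUM (1.21) of the fibroblast list were higher, so this stays open. A different state or batch of the cultured cells could not be told from a technical batch: the median of the noradrenergic list was -0.792 and that of the mesenchymal list 0.478, the latter just short of the predicted 0.5.

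The averages named LPS+2-AB in the authors' deposited table lay nearest the arrays labelled noLPS_medium. The median absolute difference was 0.142, against 0.56 from the arrays labelled 2AB_LPS, and the average named LPS lay nearest the arrays labelled 2AB_LPS (0.117). In the authors' other 2-AB table the average named LPS also lay nearest the arrays labelled noLPS_medium (0.245, against 0.463 from those labelled 2AB_LPS). The average named Control there lay nearest the arrays labelled 2AB_LPS (0.13). The negative correlation of the deposited fold with the labelled difference follows from this and is no separate evidence. Which labels are right was not tested.

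Histone and MTRNR2L features were higher in the arrays labelled noLPS_medium than in those labelled 2AB_LPS. More cells in S phase is not borne out by the G1/S and replication list, whose median was 0.101 (SD 0.25, 18 of 25 members higher in the arrays labelled 2AB_LPS). Less RNA put into labelling was tested through the spiked poly-A controls, which averaged 6.51 ± 0.51 in the arrays labelled noLPS_medium and 4.94 ± 0.14 in those labelled 2AB_LPS, while the hybridization controls, added after labelling, also differed (11.81 ± 0.43 and 10.69 ± 0.07). Over the 6 arrays of the extract set the spiked poly-A controls correlated with the histone mean at 0.361 (p = 0.479 by 720 permutations), which cannot tell. Without the 2 arrays whose spiked controls lay farthest from the median it was 0.986, from too few arrays to be read.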

How the results depend on the processing

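Of the values for single named genes, 679 kept their sign and their side of the adjusted p threshold of 0.05 under the alternatives. A further 83 kept the sign and lost the threshold, and 86 kept the sign and gained it. The sign changed in 12 that had not passed and in 10 that had passed. Size was not compared, and genes that failed both ways count among the 679. For LPS against control (18 clusters), the planned fit against the arrays labelled noLPS_medium gave 12028, with the replicate block 11981, and leaving out arrays 9 to 15. Its lists (4 passing) became 14, with the block 13, with an estimated correlation 1, with fry 1, and 2 to 6 leaving out arrays. For BBEE against control (2) the planned fit gave 12130, the block 12116, the dim filter 5, only the compared groups 0, a trend 79, and leaving out arrays 0 to 2; its lists (4) gave 14, with the block 13, with an estimated correlation 0, with fry 2, and 3 to 6. The planned fit crosses the sets by its construction. In it and with its block TNC (-0.79), FAM129A (-0.053) and CPT1A (-0.42) reversed for LPS, and CPT1A (-0.27) and INSIG1 (0.26) for BBEE.

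For BBEE under LPS (28) the single-array table gave 17, the dim filter 50, only the compared groups 7, a trend 167, the replicate block 29 and leaving out arrays 1 to 3; its lists (10) gave 3 with an estimated correlation and 7 to 12 leaving out arrays. For LPS under BBEE (1) the single-array table gave 3, quantile normalization 2, the dim filter 4, only the compared groups 2, the replicate block 2, a trend 6 and leaving out arrays 1 to 2; its lists (4) gave 1 with an estimated correlation, 2 with fry and 1 to 5. For the interaction (0) the planned fit gave 8806, the block 8741, the dim filter 2 (VCAM1 and CCL2), a trend 2 (CCL2 and CPT1A) and leaving out arrays 0; its lists (3) gave 11, with the block 11, with an estimated correlation 0, with fry 1, and 1 to 5. For the 2-AB set (2) quantile normalization gave 6, loess 4, the dim filter 17, only the compared groups 0, a trend 272, the replicate block 2 and leaving out arrays 1 to 218; its lists (4) gave 1 with quantile, loess or the dim filter, 0 with an estimated correlation or fry, and 1 to 5.

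Across the sets, the arrays labelled 2AB_LPS against LPS (9630 higher, 1908 lower) gave 4406 and 4602 after quantile normalization and 4645 and 4439 after loess, and BBEE with LPS against 2AB_LPS (1868 and 9499) gave 4701 and 4325, then 4344 and 4609. The median over all clusters went from 0.519 to -0.021 and -0.001, and from -0.508 to 0.041 and 0.011. The replicate block gave 11539 and 11349 clusters, and leaving out arrays 8761 to 9550 and 8580 to 9658. Their lists (13 and 12) gave 3 and 0 with an estimated correlation and 26 and 25 with fry. Correlations between comparisons became 0.236 (BBEE without and with LPS), -0.453, 0.084 and -0.943 with the dim filter, and 0.12 for BBEE and 2-AB after quantile normalization. The dim filter tests fewer clusters and leaving out arrays uses fewer arrays. The single-array table holds the same 6 extract arrays to within 0.0503, and its spread draws on the 2 control columns in place of the 2-AB set. For BBEE under LPS it shared 16 of the 28 calls. For the other changes the cause was not tested. Replicate numbers did not pair arrays (correlations -0.072 to 0.08 over 10 group pairs). A replicate block by the column numbers of the single-array table gave 18 clusters for LPS, 1 for BBEE (INSIG1 no longer passed) and 0 for the interaction. This block, the fits within the extract set and the lists without single arrays were added after seeing the data. The single-array table was not run for the 2-AB set, which it lacks. Signal over background limits reading of genes within the olfactory range.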

Other observations

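Genes of cell lineage were among those that differed between the sets. Genes of hormone-storing vesicles, CHGA and CHGB, and the catecholamine enzyme genes DBH and DDC were lower in the arrays labelled noLPS_medium than in the control columns, while TH, the first enzyme gene of that pathway, was higher (0.71, adjusted p = 0.02). Of genes linked to mesenchymal-type cells, VIM (an intermediate filament), FN1 (fibronectin), SNAI2 (a repressor of epithelial genes) and DCN (a matrix proteoglycan), were higher. After quantile normalization of 12 arrays, CHGA differed by -4.17 (adjusted p = 3.35e-09, limma), CHGB by -4.83 (adjusted p = 5.71e-09), VIM by 3.53 (adjusted p = 2.13e-07) and DCN by 4.63 (adjusted p = 8.11e-08). As lists these genes were less clear. The noradrenergic list had 6 members passing as higher and 12 as lower of 24 (camera adjusted p = 0.0162, but adjusted p = 0.138 with an estimated correlation), and the mesenchymal list 8 and 2 of 20 (camera adjusted p = 0.0262, but adjusted p = 0.138 with an estimated correlation). GATA3 (2.04) and PHOX2A (1.32) were higher and MYCN was unchanged (-0.08, adjusted p = 0.813). Cholesterol synthesis genes were lower, 19 of 23 passing (median -2.07, camera adjusted p = 2.18e-11, and 0.0209 with an estimated correlation), fatty acid synthesis genes 11 of 11 (median -1.84, camera adjusted p = 1.69e-07, and 0.0209 with an estimated correlation), and G2/M genes were higher in 16 of 25 passing (median 0.93, camera adjusted p = 8.76e-05, and 0.0305 with an estimated correlation). CCL2 stood at 8.16 in the arrays labelled noLPS_medium and 4.39 in the control columns, the latter within the olfactory range (5.57, adjusted p = 9.91e-08). Set, batch and treatment coincide here, so a culture state and a technical batch cannot be separated.

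The comparison of sets was added after seeing the data. The authors' deposited table of LPS against control for 2-AB held 1327 rows, 0 with FDR under 0.05. Its log2 fold correlated at -0.781 with the labelled difference, 2AB_LPS minus noLPS_medium, which is by name another contrast.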
